A study of Gallus gallus with 3 samples.

How the data were processed

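Polyadenylated RNA was measured in 3 cryosections of wild-type White Leghorn chicken lung at embryonic day 5. Per the labels' protocols, sections of about 7 µm were fixed, barcoded in the tissue through crossed microfluidic channels, and sequenced as paired-end Nextera XT libraries. Each crossing of a row channel with a column channel is a pixel, and channel numbers run up to 50 in both directions. All 3 sections form 1 group, and the labels name no treatment, so every comparison was made between regions inside a section. The labels do not say whether the sections come from separate embryos. The spread between sections may therefore be technical, and no p-value below can be taken to measure a spread between embryos. The edgeR p-values also take in counting error and a dispersion shared across genes. The camera p-values compare the genes of a list with all other tested genes.

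The deposited values are raw counts per gene and pixel: every gene column held whole numbers of at least 0, and totals differed between pixels. Per the submitters' processing notes the genome build is GRCg7b. The aligner, the counting program, the annotation release, the collapsing of molecular identifiers, the criterion of the filter applied to the pixels and the physical size of a pixel are not given in the sources used here. Counts are therefore called counts and not molecules, and counting intervals cover counting error only. Gene positions were taken from the RefSeq annotation of the same build. Of 20666 gene names in any section, the 14790 shared by all 3 were used in the gene and list tests, for spatial patterning and for clusters. The remaining 5876 names held 0.1002% of the counts and were left out of those steps. They count in total counts, the region score, summed list levels and list correlations of the sections that hold them.

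A pixel was kept with at least 0.1 of its section's median count and at least 3 of its 8 neighbours present, which left 984, 1072 and 1330 pixels in sections 1, 2 and 3. Each kept pixel was scored by the counts of the list named epithelium, defining, as a share of all counts, both summed over a window of 3 by 3 pixels. Of the 20 genes fixed in that list, 15 were in at least 1 section and counted there, and 13 were in all sections. The top 20% of a section's pixels were called epithelial-high and the bottom 50% epithelial-low, and the 30% between were left out. These regions are ranges of a continuous score: 88, 101 and 84 pixels lay within 20% of the upper boundary in the 3 sections, and 112, 70 and 129 within 20% of the lower boundary. The defining genes were left out of every test and count, but not of library sizes. For the comparison by distance, steps were counted from the nearest epithelial-high pixel in a patch of at least 4 touching pixels. Pixels within 1.5 steps were left out as a buffer against mixing, and the remaining pixels that were not epithelial-high were divided by distance into 3 equal parts, the nearest called near and the farthest far.

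Counts were summed per section and region, which gave 6 libraries per comparison. Genes were filtered with filterByExpr, scaled with TMM and tested with edgeR 4.0.16 by the quasi-likelihood test with section as a block, Benjamini-Hochberg adjustment and a false discovery rate of 5%. Lists with at least 4 tested genes were tested with camera in limma 3.58.1 at a preset correlation of 0.01, and again with an estimated correlation, with Benjamini-Hochberg adjustment over the lists. Counts per pixel were compared as a ratio within each section with a two-sided exact sign-flip permutation test. Fold changes of genes with few counts in 1 region are given as the ratio of summed CPM (counts scaled to a fixed library total) with a 95% counting interval.

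The 26 lists were epithelium, defining; lung epithelium, held out; TGF-beta ligands, receptors and SMADs; TGF-beta target genes; mesenchymal condensation and cell adhesion; interstitial extracellular matrix; basement membrane; lung mesenchyme patterning; the Hedgehog, BMP, FGF, WNT and retinoic acid pathways; YAP and actomyosin; smooth muscle; endothelium; erythroid; mesothelium; neuron and neural crest; heart and skeletal muscle; immune; liver and gut; proliferation; hypoxia and glycolysis; mitochondrial genome; and stress response. Region definitions, lists, tests and most alternatives were chosen before the data were examined. The alternatives chosen after seeing the data were the largest tissue piece alone, the removal of row 24 with ribosomal RNA, epithelial-low pixels alone for near and far, and near and far matched in bands of 5 rows.

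Genes were named by a rule. For each comparison it took the 8 largest and 8 smallest fold changes among genes past the threshold with at least 20 CPM, an assigned symbol and 1 direction in all 3 sections. To these it added the 2 genes with the smallest p from each list and, in any case, TGFB1, TGFB2, TGFB3, TGFBR1, TGFBR2 and TGFBI. For spatial patterning the rule took the 10 genes with the highest mean index, and for clusters the 5 leading genes with at least 50 CPM. Some genes so chosen in lists of little change are covered by their list's counts and not named.

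Spatial patterning was measured by Moran's I of log2 CPM plus a pseudocount of 100, with 8-neighbour weights, for genes with a mean of at least 0.1 counts per pixel in every section. A gene was called when its index exceeded the largest of 100 permutations of pixel positions in each of the 3 sections. Lists were correlated across pixels that were not epithelial-high, on 3 by 3 window sums adjusted for window counts and with shared genes left out of both, and compared with 1000 random lists matched on mean expression. Leiden clusters (resolution 0.5, 15 neighbours, 20 components of 2000 variable genes) were made with scanpy 1.11.5 after centring within section, and are regions named by leading genes. Other tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, R 4.3.3 and, as an alternative test, DESeq2 1.42.0.

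The gene tests were tested on simulated data with the depth of the real libraries and 50 genes changed per size of fold. In the comparison of epithelial-high with epithelial-low pixels, 28% of genes changed 1.5-fold were recovered, 68% at 2-fold, 96% at 4-fold and 100% at 8-fold, with 9 false calls among 10624 genes. For near against far the shares were 22%, 70%, 98% and 100%, with 7 false calls among 8929 genes. For Moran's I, on 1000 simulated genes of section 1, the shares were 10%, 36%, 90% and 100%, and 1.5% of unchanged genes were called. The alternatives were other size factors, no filter, no replicate block, thinning to equal totals, DESeq2, leaving out each section, other boundaries and buffers, all deposited pixels, a score from the pixel alone, other pseudocounts and minimum counts, centring within channels, other cluster resolutions, and those named above.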

Results

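Gene expression was mapped in 3 sections of embryonic day 5 chicken lung, which form 1 group of wild-type tissue with n = 3 sections. The labels do not say whether the sections come from separate embryos, so every SD given here is a spread between sections. Each SE comes from the edgeR fit, which also takes in counting error and a dispersion shared across genes. Section values can spread more widely than the SE. Section 1 held 1018 pixels and 5163258 counts, section 2 held 1091 pixels and 4306194 counts, and section 3 held 1421 pixels and 11548560 counts. The median pixel held 4659.5, 3423 and 7727 counts in sections 1, 2 and 3, from 1981.5, 1478 and 2573 genes. Annotated ribosomal RNA genes took 20.0% of the counts in section 1 (95% Wilson interval 20.0 to 20.1), 23.95% in section 2 (23.91 to 23.99) and 26.8% in section 3 (26.7 to 26.8). In row channel 24 the median ribosomal share per pixel was 57.8%, 56.7% and 55.2% in the 3 sections, against 18.1%, 21.7% and 24.3% at the median of the other rows and 32.3%, 47.7% and 37.8% in the highest of them. The single gene FRMD8 took 1.66% of the counts in section 1 (95% Wilson interval 1.65 to 1.67), 1.76% in section 2 (1.75 to 1.775) and 3.29% in section 3 (3.28 to 3.30).

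Epithelial-high regions held 197, 215 and 266 pixels in sections 1, 2 and 3, and epithelial-low regions held 492, 536 and 665. The defining epithelial genes, which were left out of every test, summed to 1816 ± 445 CPM (SD, n = 3) in epithelial-high and 74.0 ± 27.9 CPM in epithelial-low pixels. Near regions held 207, 223 and 301 pixels and far regions 226, 221 and 294. The mean distance to the nearest epithelial-high patch was 2.40, 2.29 and 2.53 pixel steps in near regions and 7.70, 5.65 and 8.95 steps in far regions. Section 3 held a main tissue piece of 1327 pixels and separate pieces of 48 and 46 pixels. The 46-pixel piece, with 26 of the epithelial-high pixels, carried liver transcripts such as FGB at 727 CPM and no NKX2-1 count, and 40 of the far pixels lay in the 48-pixel piece.

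**Figure D1:**
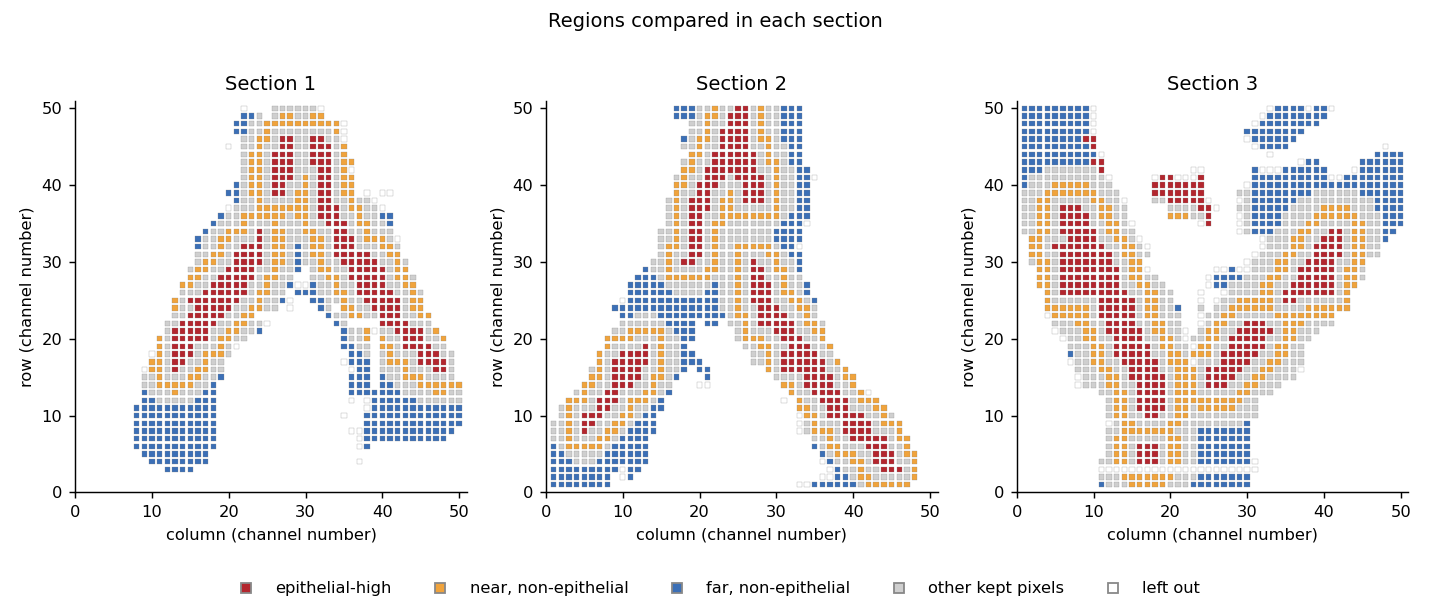
Maps of the 3 sections by column channel and row channel number, with each pixel colored as epithelial-high, near, far, other kept or left out. Epithelial-high pixels form compact patches, 197, 215 and 266 pixels in sections 1, 2 and 3.

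The series title names TGF-beta, epithelial spacing and mesenchymal condensation. The comparison of epithelial-high with epithelial-low pixels asks which genes separate tissue rich in epithelial genes, not airway alone, from the tissue around it. Epithelial-high pixels held more of NKX2-1, FOXA2 and WNT7B and less of BARX1 and TGFB2. NKX2-1, the transcription factor that specifies lung epithelium, reached 105 ± 24.01 CPM (SD, n = 3) in epithelial-high against 0.304 ± 0.373 CPM in epithelial-low pixels. FOXA2, a pioneer factor of endoderm, reached 136 ± 34.1 against 1.27 ± 0.811 CPM, and WNT7B, a WNT ligand of lung epithelium, 119 ± 19.2 against 0.622 ± 0.770 CPM. BARX1, a homeobox factor of foregut mesenchyme, stood at 154 ± 62.9 CPM in epithelial-low against 8.18 ± 4.92 CPM in epithelial-high pixels. The ligand TGFB2 was lower in epithelial-high pixels, 106 ± 29.0 against 287 ± 60.6 CPM, a log2 fold change of -1.40 ± 0.13 (SE, n = 3).

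Of 10624 genes tested with edgeR, 2611 passed, 1336 higher and 1275 lower in epithelial-high pixels. The genes with the largest positive log2 fold changes were CYP2C23a, a cytochrome P450 gene (8.40 ± 0.35, SE, n = 3), VSIG1 (8.15 ± 0.49), NKX2-1 (8.11 ± 0.32), WNT7B (7.67 ± 0.32), MAP7 (7.11 ± 0.30), FOXA2 (6.89 ± 0.26), RAB2B (6.61 ± 0.42) and TF, which encodes transferrin (6.41 ± 0.19). Those with the largest negative values were EBF3 (-5.76 ± 0.45), FOXD3, a neural crest factor (-4.74 ± 0.42), HOXB6 (-4.50 ± 0.27), BARX1 (-4.17 ± 0.19), THBD (-4.00 ± 0.26), PITX1 (-3.56 ± 0.28), MXRA5 (-3.46 ± 0.29) and MYLK, the myosin light chain kinase (-3.46 ± 0.21). All 16 had the same direction in 3 of 3 sections, as the naming rule required. Where 1 region held few counts, the ratio of summed CPM with its 95% counting interval was 417 (115 to 3458) for CYP2C23a, 425 (75.4 to 16887) for VSIG1, 317 (108 to 1545) for NKX2-1 and 223 (94.8 to 689) for WNT7B. The ratio of epithelial-low over epithelial-high was 60.1 (20.4 to 293) for EBF3 and 29.9 (12.7 to 92.5) for FOXD3. The ligand SHH had 3, 2 and 4 counts in the epithelial-high regions of sections 1, 2 and 3 and no count in epithelial-low, near or far regions, too few for a test.

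On the GRCg7b assembly, CYP2C23a (gene ID 414746) spans chromosome 6 from 18351042 to 18358414, with an edgeR adjusted p of 9.26e-13. NKX2-1 (395322) spans chromosome 5 from 36137640 to 36144955, with an edgeR adjusted p of 6.51e-13. TF (396241) spans chromosome 9 from 4254973 to 4265744, with an edgeR adjusted p of 7.76e-15. BARX1 (374017) spans chromosome 12 from 6318419 to 6320900, with an edgeR adjusted p of 2.63e-12. EBF3 (395175) spans chromosome 6 from 34940430 to 35060617, with an edgeR adjusted p of 4.57e-09. TGFB2 (421352) spans chromosome 3 from 19040842 to 19104266, with an edgeR adjusted p of 1.21e-07. All 6 are annotated as protein-coding genes. Of the 74 genes named in the gene comparisons, 31 overlap another annotated gene, with TGFB2, TGFB3, TGFBR1 and LTBP1 among them. Overlap was taken on whole gene spans without regard to strand or exons, so the origin of their counts may be uncertain. For 11 of them the other gene is protein-coding: DACT2, FOXA2, HOXB5, HOXB6, HSPA2, KCNIP4, MAP7, NKX2-1, RAB2B, RSPO3 and TBX4. HOXB5 and HOXB6 overlap each other and HOXB3.

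Of 15 tested genes in the list of lung epithelium held out from the region score, 10 were higher and 1 lower in epithelial-high pixels over all genes, and 12 higher and 1 lower adjusted over the list alone. FGFR2, the receptor for FGF10, was higher (2.13 ± 0.14, SE, n = 3) and ETV5, a transcription factor of FGF signaling, was lower (-0.56 ± 0.13). ETV5 had an edgeR adjusted p of 0.00339, which was 0.0728 without section 1 and ranged from 0.000325 to 0.0728 over its alternatives. The camera test placed the list higher with an adjusted p of 3.66e-25, and the adjusted p was 0.123 with an estimated correlation.

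Of 19 tested genes in the list of TGF-beta ligands, receptors and SMADs, 10 were lower over all genes in edgeR, and 11 adjusted over the list alone, while DESeq2 called 4. LTBP1, which holds latent TGF-beta in the matrix, was lower (-1.44 ± 0.14, SE, n = 3), at 83.4 ± 18.2 against 231 ± 14.9 CPM. TGFB3 was lower at 43.8 ± 13.6 against 70.2 ± 2.64 CPM (-0.67 ± 0.17), as was the receptor TGFBR1 at 107 ± 19.5 against 147 ± 24.96 CPM (-0.46 ± 0.12), each in 3 of 3 sections. The TGFB3 edgeR adjusted p was 0.0046, and over its alternatives adjusted p ranged from 0.000217 to 0.0563. The TGFBR1 edgeR adjusted p was 0.00955, which was 0.0583 without section 1 and 0.15 without the section block, in a range from 0.00189 to 0.15. The receptor TGFBR2 did not pass, with a log2 fold change of -0.64 ± 0.43 and an edgeR adjusted p of 0.328. TGFB1 had 4, 3 and 1 counts in the epithelial-high regions of sections 1, 2 and 3 and 13, 5 and 8 in the epithelial-low regions, too few for a test. The list was placed lower by camera with an adjusted p of 0.00038, and the adjusted p was 0.314 with an estimated correlation. Of 13 tested TGF-beta target genes, 3 were higher and 4 lower, the same adjusted over the list alone, and the camera adjusted p was 0.45. Among them TNC, the matrix glycoprotein tenascin C, was higher (2.41 ± 0.17), POSTN, which encodes periostin, was lower (-3.16 ± 0.24), and TGFBI did not pass (0.63 ± 0.36, edgeR adjusted p of 0.233).

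Camera placed the condensation, interstitial matrix, mesenchyme patterning and smooth muscle lists lower in epithelial-high pixels, while basement membrane and YAP and actomyosin did not pass. In the list of mesenchymal condensation and cell adhesion, 4 of 17 tested genes were higher, with TNC among them, and 10 lower, with BARX1 and the proteoglycan gene VCAN (-1.91 ± 0.13, SE, n = 3) among them. Its camera adjusted p was 0.000693, and the adjusted p was 0.24 with an estimated correlation. In interstitial extracellular matrix 19 of 21 genes were lower, such as the collagen genes COL1A2 (-1.73 ± 0.10) and COL1A1 (-1.53 ± 0.10), with a camera adjusted p of 9.5e-20 and an adjusted p of 0.123 with an estimated correlation. In lung mesenchyme patterning 15 of 18 genes were lower, such as MEIS1 (-1.94 ± 0.11) and HOXB5 (-2.21 ± 0.14), with a camera adjusted p of 1.49e-20 and an adjusted p of 0.123 with an estimated correlation. Basement membrane genes went both ways, 8 of 19 higher and 6 lower, or 7 lower adjusted over the list alone, with a camera adjusted p of 0.528. FREM2 was higher (3.40 ± 0.17) and the laminin gene LAMB1 lower (-1.37 ± 0.12). In smooth muscle 3 of 7 genes were lower, with CALD1, which encodes caldesmon (-1.68 ± 0.13), and MYLK among them, with a camera adjusted p of 0.000693 and an adjusted p of 0.24 with an estimated correlation. Of 14 genes of YAP and actomyosin 1 was higher and 5 lower, such as the myosin gene MYH10 (-0.69 ± 0.08), with a camera adjusted p of 0.06.

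Signaling lists were mixed. In the Hedgehog pathway 1 of 8 genes was higher and 6 lower, such as the coreceptor GAS1 (-2.64 ± 0.21, SE, n = 3) and the transcription factor GLI3 (-1.41 ± 0.14), with a camera adjusted p of 0.000693 and an adjusted p of 0.314 with an estimated correlation. In the retinoic acid pathway 1 of 8 genes was higher and 5 lower, such as CRABP1, a retinoic acid binding protein (-2.65 ± 0.12), and the synthesis enzyme ALDH1A2 (-1.60 ± 0.15), with a camera adjusted p of 0.000584 and an adjusted p of 0.351 with an estimated correlation. With the epithelial score taken from the pixel alone, ALDH1A2 stood at 0.32 with an edgeR adjusted p of 0.0802, in a range from 8.34e-26 to 0.0802 over its alternatives. Of 17 BMP pathway genes 4 were higher, such as ID3 (0.71 ± 0.09), and 7 lower, or 8 lower adjusted over the list alone, with a camera adjusted p of 0.233. Of 12 FGF pathway genes 1, FGFR2, was higher and 4 lower, or 2 higher adjusted over the list alone, with a camera adjusted p of 0.743. Of 14 WNT pathway genes 3 were higher, such as WNT7B, and 6 lower, such as WNT2B, a ligand of lung mesenchyme (-2.30 ± 0.19), or 7 lower adjusted over the list alone, with a camera adjusted p of 0.528.

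Endothelium and erythroid lists were placed lower in epithelial-high pixels, and mesothelium, neuron and the lists of cell state did not pass. In endothelium 12 of 14 genes were lower, such as the transcription factor ERG (-2.45 ± 0.15, SE, n = 3) and the cadherin CDH5 (-2.93 ± 0.25), with a camera adjusted p of 3.89e-10 and an adjusted p of 0.135 with an estimated correlation. All 6 tested erythroid genes were lower in edgeR, such as the globin gene HBBR (-2.36 ± 0.33), with a camera adjusted p of 4.46e-05 and an adjusted p of 0.39 with an estimated correlation. DESeq2 called 2 of these 6, and HBBR stood at -2.49, -0.70 and -3.82 in sections 1, 2 and 3. Of 8 mesothelium genes 3 were higher, with UPK1B (6.07 ± 0.28) among them, and 5 lower, with a camera adjusted p of 0.528. Of 10 genes of neuron and neural crest 2 were higher and 5 lower, with a camera adjusted p of 0.218. In hypoxia and glycolysis 5 of 12 genes were higher, such as lactate dehydrogenase LDHA (1.84 ± 0.20) and carbonic anhydrase CA9 (1.22 ± 0.14), with a camera adjusted p of 0.06. In stress response 3 of 10 genes were higher, such as HSPA2 (1.63 ± 0.17), with a camera adjusted p of 0.241. In the mitochondrial genome 4 of 11 genes were higher in edgeR, or 5 adjusted over the list alone, while DESeq2 called 0, with a camera adjusted p of 0.272. Of 23 proliferation genes 2 were higher and 2 lower over all genes in edgeR, with a camera adjusted p of 0.331. Adjusted over the list alone 0 passed, with 7 at an unadjusted p under 0.05 in edgeR and 0 called by DESeq2.

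For condensation, interstitial matrix, mesenchyme patterning, smooth muscle, YAP, Hedgehog, retinoic acid, endothelium, erythroid, mesothelium, neuron, hypoxia and stress lists, the counts adjusted over the list alone were those given over all genes. Camera placed 10 of 22 lists past its threshold, 1 higher and 9 lower, and 0 with an estimated correlation, where the smallest adjusted p was 0.123. Median, mean and test differed in sign for WNT (median -0.34, mean 0.04, test lower), mesothelium (-1.43, 0.07, lower), stress response (-0.05, 0.35, higher) and FGF (0.03, -0.17, higher). The lists of heart and skeletal muscle, immune, and liver and gut genes had too few tested genes. They summed to 39.96 ± 7.27 (SD, n = 3), 20.7 ± 0.676 and 281 ± 481 CPM in epithelial-high pixels and to 51.9 ± 12.1, 33.1 ± 5.25 and 18.1 ± 7.48 CPM in epithelial-low pixels. The liver and gut value rests on section 3, at 836 CPM, while sections 1 and 2 stood at 4.98 and 2.48 CPM in epithelial-high against 26.3 and 16.1 CPM in epithelial-low pixels. Of the 13 genes of that list 11 were in at least 1 section and 3 in all. APOB, TTR, FGG and FGA were listed for section 3 alone and count in its value. Across 6698 genes, fold changes of section pairs correlated with r of 0.817, 0.823 and 0.787, and genes are not independent replicates. Counts per pixel in epithelial-high over epithelial-low were 0.958, 0.979 and 1.18 in the 3 sections, with a two-sided exact permutation p of 1 (n = 3, smallest possible 0.25). The count of 2611 genes fell to 1734 without section 1, to 1445 in DESeq2 and to 1463 without the section block.

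**Figure D2:**
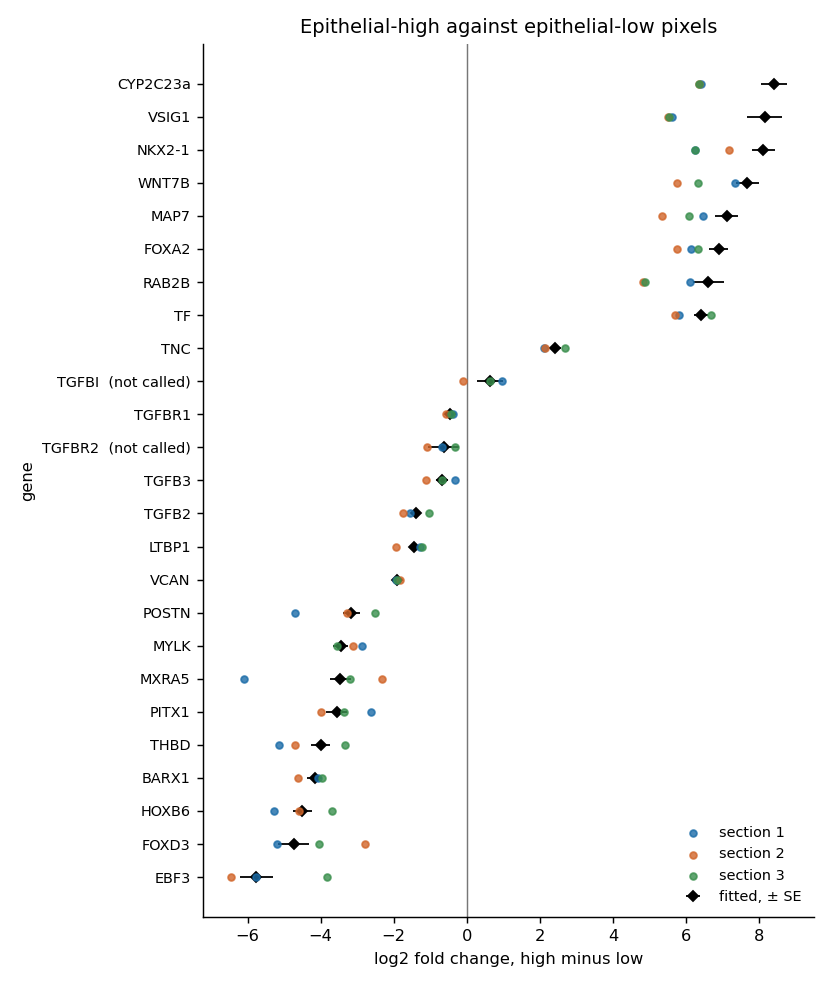
Log2 fold change, epithelial-high over epithelial-low pixels (x axis), of named genes (y axis): colored dots are the 3 sections, black diamonds the edgeR fitted values with SE. Section values use a prior count and lie nearer 0 for genes almost absent from 1 region, and NKX2-1 at 8.11 and EBF3 at -5.76 lie near the ends of the range.

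The comparison of near with far pixels asks how the tissue around the epithelium changes with distance from it. Near pixels were rich in CYP1B1, a cytochrome P450 enzyme gene, at 363 ± 81.0 CPM (SD, n = 3) against 78.8 ± 26.4 CPM in far pixels. SOX9, a transcription factor of skeletal condensations and of distal lung epithelium, stood at 136 ± 17.3 near and 28.5 ± 25.7 CPM far, and SNAI2, a mesenchymal transcription factor, at 261 ± 18.3 near and 113 ± 35.0 CPM far. Far pixels were rich in HOXB6, at 189 ± 109 CPM against 42.8 ± 3.01 CPM near, and in FN1, which encodes fibronectin, at 323 ± 81.0 against 147 ± 21.7 CPM near. TGFB2 stood at 279 ± 36.8 CPM near and 432 ± 146 CPM far, lower near in 3 of 3 sections, and did not pass (log2 fold change -0.59 ± 0.15, SE, n = 3, edgeR adjusted p of 0.0789). Its section values were -1.10, -0.48 and -0.19. It passed under 6 alternatives, 3 of them chosen after seeing the data, and the edgeR adjusted p ranged from 0.000185 with no filter to 0.64 without section 1. TGFB1 had 1, 3 and 2 counts near and 4, 2 and 4 far in sections 1, 2 and 3, too few for a test.

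Of 8929 genes tested with edgeR, 127 passed, 82 higher and 45 lower near the epithelium, and 1100 had an unadjusted p under 0.05. The largest positive log2 fold changes were those of HECW1, a ubiquitin ligase gene (2.42 ± 0.23, SE, n = 3), CYP1B1 (2.24 ± 0.21), SOX9 (2.19 ± 0.33), GATA4, a factor of foregut and heart mesoderm (2.05 ± 0.30), DBX2 (1.97 ± 0.31), the WNT ligand WNT11 (1.91 ± 0.24), KCNIP4 (1.90 ± 0.23) and FREM1 (1.82 ± 0.16). The largest negative ones were those of the WNT ligand WNT4 (-2.99 ± 0.52), HS3ST3B1L (-2.56 ± 0.47), HOXB6 (-2.02 ± 0.20), DACT2 (-1.93 ± 0.37), the WNT agonist RSPO1 (-1.69 ± 0.26), MLLT3 (-1.68 ± 0.28), the semaphorin SEMA3C (-1.56 ± 0.31) and SYNDIG1 (-1.54 ± 0.24). These 16 genes had the same direction in 3 of 3 sections, as the naming rule required. Section values could still lie far apart, as for HS3ST3B1L at -3.97, -0.21 and -2.28. SOX9 was also higher in epithelial-high than in near pixels, by a mean log2 ratio of 0.40. HECW1 (gene ID 420774, chromosome 2, 51260079 to 51496812) and CYP1B1 (421466, chromosome 3, 31601061 to 31606889) both had an edgeR adjusted p of 0.000307. FREM1 (427355, chromosome Z, 32157804 to 32227113) had an edgeR adjusted p of 0.000204. HOXB6 (777548, chromosome 27, 3412953 to 3423449) had an edgeR adjusted p of 0.00039, and WNT4 (395561, chromosome 21, 6295870 to 6309892) one of 0.0136.

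Camera placed lung mesenchyme patterning, interstitial matrix, WNT, retinoic acid and endothelium lists higher near the epithelium, each at a preset correlation alone. In lung mesenchyme patterning 3 of 17 genes were higher, or 6 higher and 1 lower adjusted over the list alone, with TBX2 (0.83 ± 0.13, SE, n = 3) and TBX4 (0.77 ± 0.16), both T-box factors, among them. Its camera adjusted p was 0.00281, and the adjusted p was 0.658 with an estimated correlation. In interstitial extracellular matrix 2 of 20 genes, the collagen gene COL3A1 (1.24 ± 0.26) and FBLN1 (0.95 ± 0.22), were higher and 1 lower, or 6 higher and 1 lower adjusted over the list alone. Its camera adjusted p was 0.0115, and the adjusted p was 0.658 with an estimated correlation. In section 2 the log2 folds of COL3A1 and FBLN1 were 0.012 and 0.020, and the list stood at 3330 CPM near against 3288 CPM far. Matched in bands of 5 rows, the test placed interstitial matrix and the retinoic acid pathway lower near, although their median log2 folds stayed positive (0.0268 and 0.142). In the WNT pathway 3 of 13 genes were higher, such as WNT11, and 1, the agonist RSPO3 (-0.80 ± 0.15), lower, or 3 higher and 2 lower adjusted over the list alone. Its camera adjusted p was 0.0463, and the adjusted p was 0.658 with an estimated correlation. In summed CPM the WNT list was lower near in section 3, at 796 against 893 CPM. In the retinoic acid pathway 1 of 7 genes, the receptor RXRA (0.90 ± 0.20), was higher, or 3 adjusted over the list alone, with a camera adjusted p of 0.0115 and an adjusted p of 0.658 with an estimated correlation. In summed CPM that list stood at 1344, 1037 and 992 near against 835, 1001 and 982 far in sections 1, 2 and 3. The endothelium list was placed higher with a camera adjusted p of 0.0463, and the adjusted p was 0.658 with an estimated correlation. In summed CPM it was lower near in section 3, at 421 against 489 CPM. In neuron and neural crest 1 of 9 genes was lower, or 2 adjusted over the list alone, and the list was placed lower with a camera adjusted p of 0.0115 and an adjusted p of 0.658 with an estimated correlation. With a buffer of 2.5 steps the direction of that test reversed (median log2 fold 0.053), and in summed CPM the list was higher near in section 3, at 403 against 389.6 CPM. DESeq2 called 1 gene each in lung mesenchyme patterning and WNT. It called 0 in interstitial matrix, retinoic acid, endothelium, and neuron and neural crest.

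The other lists did not pass in the near and far comparison. In mesenchymal condensation and cell adhesion 1 of 15 genes, SOX9, was higher and 2 lower, with FN1 (-1.14 ± 0.16, SE, n = 3) among them, or 5 higher and 3 lower adjusted over the list alone, with a camera adjusted p of 0.442. Of 12 TGF-beta target genes 1, SNAI2 (1.21 ± 0.17), was higher and 1, FN1, lower, or 1 higher and 2 lower adjusted over the list alone, with a camera adjusted p of 0.767. In the BMP pathway 2 of 16 genes, the ligands BMP5 (1.29 ± 0.19) and BMP4 (1.47 ± 0.23), were higher, or 3 higher and 3 lower adjusted over the list alone, with a camera adjusted p of 0.401. FGFR3, an FGF receptor (1.70 ± 0.26), was the 1 gene higher among 12 of the FGF pathway and among 8 of the held-out lung epithelium, with camera adjusted p of 0.511 for both. Adjusted over the list alone these were 3 higher and 2 lower in FGF and 2 higher and 2 lower in lung epithelium. In basement membrane 1 of 18 genes, FREM1, was higher, or 3 higher and 2 lower adjusted over the list alone, with a camera adjusted p of 0.511. In smooth muscle 1 of 6 genes, CALD1 (0.51 ± 0.10), was higher, or 1 higher and 1 lower adjusted over the list alone, with a camera adjusted p of 0.841. DESeq2 called 0 genes in the FGF, held-out lung epithelium and smooth muscle lists. It called 1 in basement membrane and 2 each in condensation, TGF-beta targets and BMP.

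Among 18 tested genes of TGF-beta ligands, receptors and SMADs, edgeR called 0 over all genes and DESeq2 called 0, with 4 at an unadjusted p under 0.05 in edgeR and 1 higher and 1 lower adjusted over the list alone. The list's camera adjusted p was 0.479. TGFBR1 stood at 167 ± 33.6 CPM (SD, n = 3) near and 119 ± 15.3 CPM far, with an edgeR adjusted p of 0.0795 in a range from 0.028 to 0.825 over its alternatives. TGFB3 stood at 76.0 ± 10.5 CPM near and 92.1 ± 13.7 CPM far, lower in 2 of 3 sections, with an edgeR adjusted p of 0.458. TGFBR2, with 11, 7 and 8 counts near and 4, 5 and 22 far in sections 1, 2 and 3, and the target gene TGFBI, with 10, 8 and 10 near and 3, 4 and 11 far, had too few counts for a test. In 9 further lists both tools also called 0 genes over all genes. Their counts at an unadjusted p under 0.05 in edgeR were 4 of 6 for mesothelium, 3 of 14 for YAP and actomyosin, 2 of 11 for hypoxia and glycolysis and 2 of 9 for stress response. They were 1 each for the Hedgehog pathway (8 genes), endothelium (14), proliferation (23) and the mitochondrial genome (11), and 0 of 6 for erythroid. Adjusted over the list alone, mesothelium had 1 higher and 1 lower, stress response had 1 higher, and edgeR called 0 in the other 7. Camera adjusted p was 0.28 for mesothelium, 0.511 for YAP and for Hedgehog, 0.149 for hypoxia, 0.365 for stress response, 0.829 for proliferation, 0.307 for the mitochondrial genome and 0.514 for erythroid.

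Camera placed 6 of 22 lists past its threshold for near against far, 5 higher and 1 lower, and 0 with an estimated correlation, where the smallest adjusted p was 0.658. Median, mean and test differed in sign for lung epithelium (median -0.12, mean 0.11, test higher), TGF-beta targets (0.02, -0.06, lower), BMP (-0.04, 0.15, higher), FGF (-0.03, 0.12, higher) and YAP (0.03, -0.10, lower). Untested lists stood at 43.5 ± 4.68 CPM (SD, n = 3) near and 49.3 ± 19.0 far for heart and skeletal muscle, 33.5 ± 4.78 and 25.7 ± 12.1 for immune, and 15.1 ± 6.65 and 21.3 ± 4.39 for liver and gut. The mesothelium list, which did not pass, stood at 371 ± 29.2 CPM near and 444 ± 39.0 CPM far. Counts per pixel were higher near than far in 3 of 3 sections, at a ratio of 1.17, 1.04 and 1.11, with a two-sided exact permutation p of 0.25 (n = 3), the smallest the design allows. Across 6582 genes, fold changes of section pairs correlated with r of 0.141, 0.419 and 0.193. Near and far regions also differed in place: their median rows were 31 and 10 in section 1, 21 and 23 in section 2, and 23 and 41 in section 3. Matched in bands of 5 rows, 97 genes passed, 39 higher and 58 lower near, and 39 of the 97 were among the 127. Without section 1 edgeR called 0 genes, with 760 of 9814 tested at an unadjusted p under 0.05, where 5% would lie by chance. Without section 2, 56 genes passed, and without section 3, 64. DESeq2 called 38 genes, edgeR without the section block 2, and edgeR on the largest tissue piece alone 72.

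**Figure D3:**
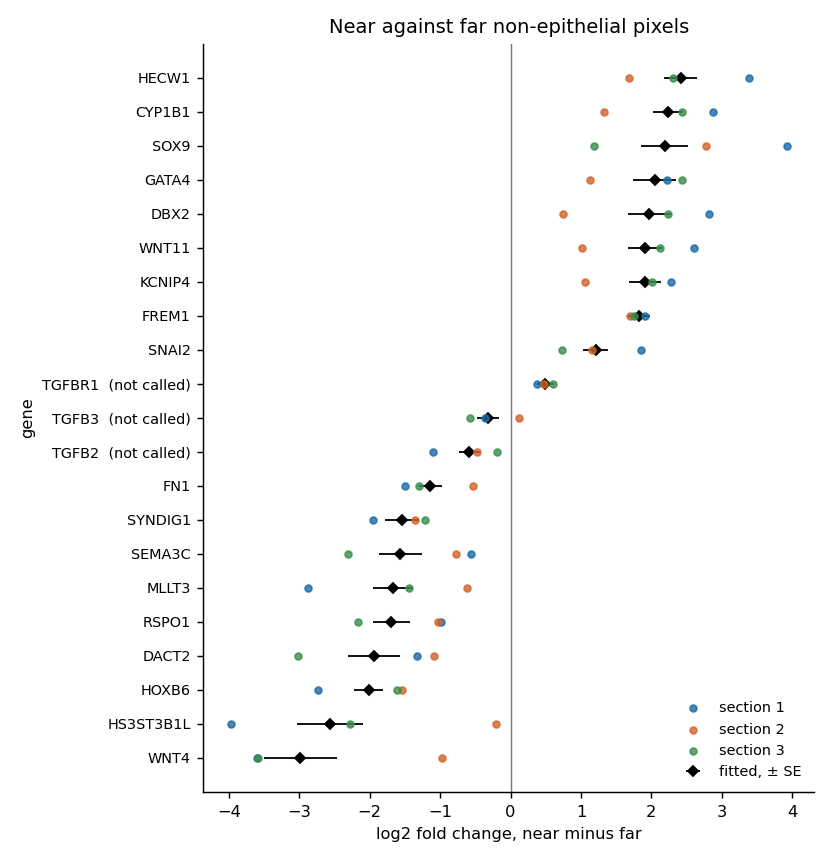
Log2 fold change, near over far pixels (x axis), of named genes (y axis): colored dots are the 3 sections, black diamonds the edgeR fitted values with SE, and genes that did not pass are marked as not called. The fitted value of HECW1 lies highest at 2.42 and that of WNT4 lowest at -2.99.

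Profiles by distance gave the levels of some genes and lists in finer steps, without a test. Of the genes given here, neither WNT2B nor PTCH1 was among those that passed between near and far. TGFB2 stood at 105 ± 30.2 CPM (SD, n = 3) in epithelial-high pixels, 219 ± 70.6 within 1.5 steps, 308 ± 67.7 from 3.5 to 4.5 steps and 464 ± 203 beyond 7.5 steps. That last bin held 13 pixels in section 2, and the bin before it, from 5.5 to 7.5 steps, stood at 389 ± 166 CPM. WNT2B went from 20.6 ± 5.35 in epithelial-high pixels through 80.8 ± 17.7 from 1.5 to 2.5 steps to 165 ± 43.3 CPM beyond 7.5 steps. TGFBR1 stood at 106 ± 16.4 CPM in epithelial-high pixels, 175 ± 44.8 within 1.5 steps, 174 ± 22.7 from 1.5 to 2.5 steps and 111 ± 26.9 beyond 7.5 steps, and its highest bin differed between the sections. The condensation list had its highest value within 1.5 steps in 3 of 3 sections, 2429 ± 169 CPM, against 1624 ± 228 in epithelial-high pixels and 2083 ± 185 beyond 7.5 steps. Interstitial matrix went from 1737 ± 458 CPM in epithelial-high pixels to 4410 ± 848 from 2.5 to 3.5 steps and stood at 2817 ± 674 beyond 7.5 steps. PTCH1, the Hedgehog receptor and target gene, stood at 122 ± 5.30 CPM within 1.5 steps against 71.0 ± 14.3 in epithelial-high pixels and 84.0 ± 20.8 from 1.5 to 2.5 steps.

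**Figure D4:**
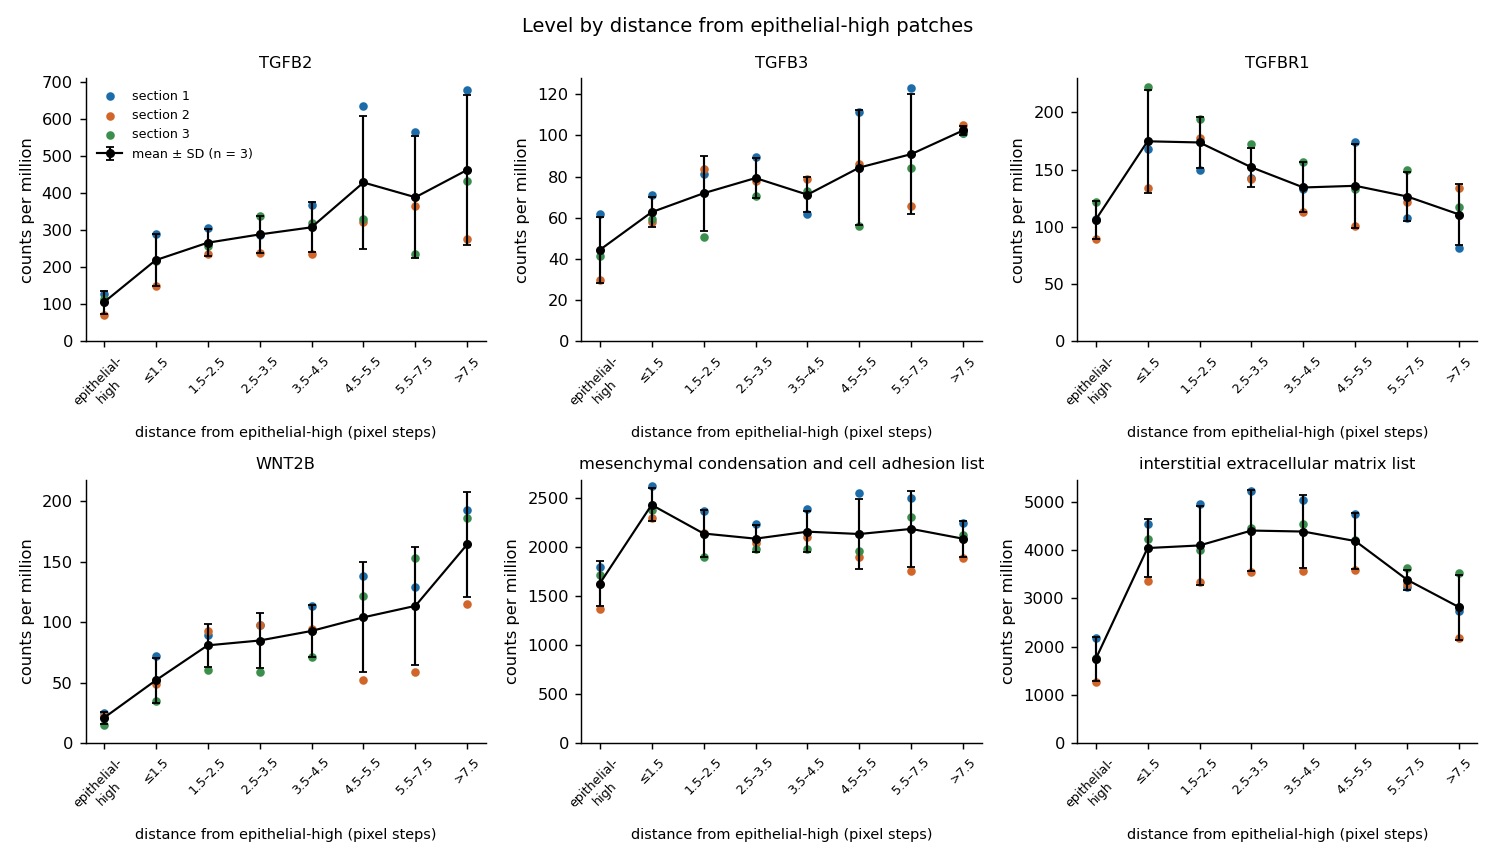
CPM (y axis) by distance from the nearest epithelial-high patch in pixel steps (x axis) for TGFB2, TGFB3, TGFBR1, WNT2B and the condensation and interstitial matrix lists. Colored points are sections and the black line the mean with SD (n = 3), and the TGFB2 mean lies at 105 CPM in epithelial-high pixels and at 464 CPM in the farthest bin.

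Whether TGF-beta genes and condensation genes rise in the same pixels was tested across pixels that were not epithelial-high. The correlation of the 2 lists was 0.0533 ± 0.0744 (SD, n = 3), with r of 0.0110, 0.139 and 0.00956 in the sections. It lay at percentile 24.8 of 1000 random lists matched on expression, whose median was 0.1 and whose 95th percentile was 0.208, so it was not higher than that of random lists. Of 23 lists and 4 genes correlated with condensation in this way, mesothelium had the lowest value, -0.283 ± 0.0789, and the mitochondrial genome the highest, 0.265 ± 0.107. YAP and actomyosin stood at 0.187 ± 0.0315, interstitial matrix at 0.166 ± 0.0469, TGF-beta targets at 0.141 ± 0.0113, LTBP1 at 0.121 ± 0.0296 and TGFB2 at -0.141 ± 0.0640. Neighbouring pixels share window counts, so pixels are not independent and no p is given. With epithelial-high pixels included the correlation was 0.281.

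Spatial patterning was called for 728 of 5722 genes (12.7%). The 10 highest mean values of Moran's I included PITX1 (0.578 ± 0.0435, SD, n = 3), HOXB5 (0.510 ± 0.0263), BARX1 (0.505 ± 0.0971) and the orphan nuclear receptor NR2F2 (0.476 ± 0.0188). The others were CYP1B1 (0.508 ± 0.0311), SMOC2 (0.506 ± 0.0612), FRMD8 (0.488 ± 0.0652), CLDN1 (0.487 ± 0.0725), APCDD1L (0.471 ± 0.149) and KCTD12 (0.468 ± 0.0321), with CLDN1 a gene of the region score. Sections alone gave 1239, 1046 and 2056 genes. After centring within row and column channels, 278 of the 728 genes were called, and 367 genes passed at a mean of at least 0.5 counts per pixel.

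Clustering gave 11 regions, most of them described by leading genes. Region 5, led by CLDN1, SOX21, WNT7B, EPCAM and NKX2-1, took 18.0 ± 4.10% of pixels (SD, n = 3), and 86.8% of its pixels were epithelial-high. Region 1 was led by the globin genes HBE, HBZ and HBBR (15.1 ± 1.30%), and region 2 by PODXL, ACPP and ALDH1A2 (10.8 ± 1.09%). Region 3 was led by HOXB8, SALL1 and HOXB6 (9.04 ± 2.36%), and region 4 by NCAM2, GRIK2 and the Hedgehog target HHIP (7.496 ± 1.85%). Region 6, led by KCNIP4, CXCL12 and CYP1B1 (11.9 ± 1.08%), had 36.5% of its pixels in the near and 6.13% in the far region. Region 7 was led by PITX1, at 326 CPM inside and 9.25 CPM outside (7.58 ± 1.501%), and region 8 by EBF3 (13.4 ± 6.29%), with EBF3 at 169 inside and 7.56 CPM outside. Region 9, led by the neural crest genes FOXD3 and SOX10 (3.995 ± 1.602%), had FOXD3 at 495 inside and 6.77 CPM outside. Region 10 had 80 of its 83 pixels in section 3, and region 11, led by FGB and BHMT2, had all of its 23 pixels there. In row channel 24, rich in ribosomal RNA, 59 of 91 pixels (64.8%) fell in region 2. Other resolutions gave 7 and 14 regions, and leading genes define the regions, so their levels are descriptions and not tests.

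**Figure D5:**
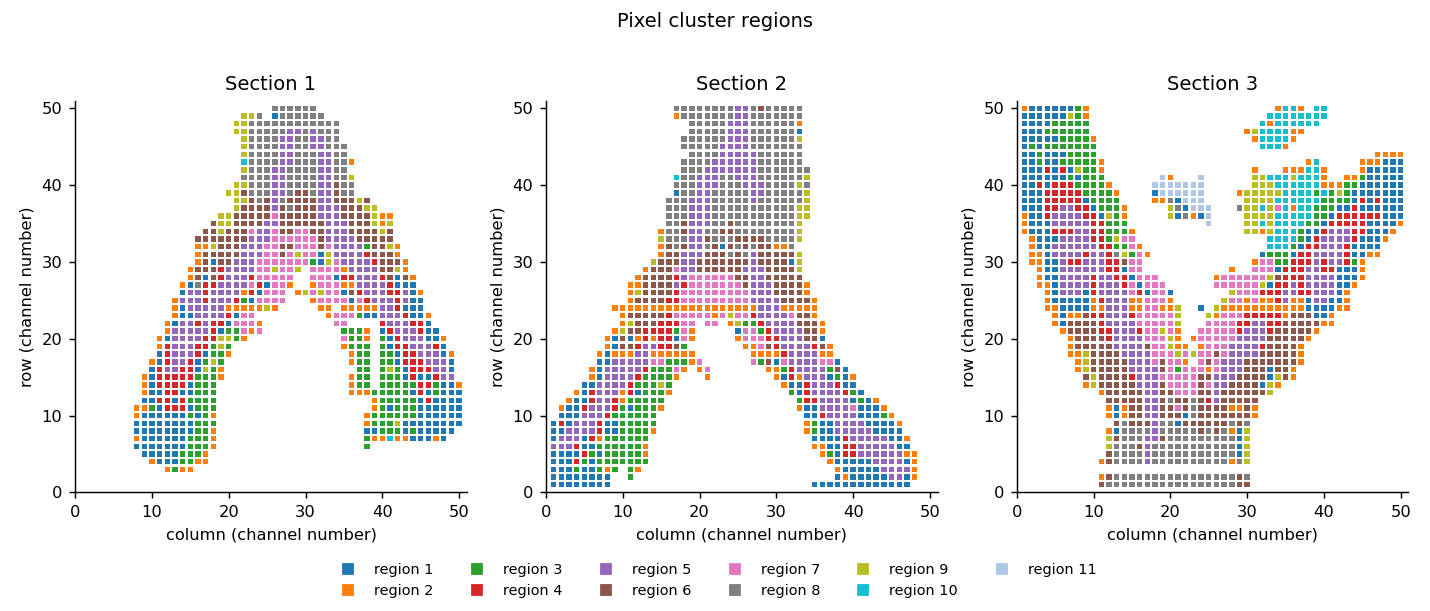
Maps of the 3 sections by column channel and row channel number, with each pixel colored by its cluster region. Region 5 covers the patches of epithelial-high pixels, and regions 10 and 11 lie almost wholly in section 3.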

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

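The values here come from gene names listed for section 3 alone, which no gene or list test uses. The criterion of at least 100 counts for naming them was chosen after the data were seen. APOB, TTR, FGG and FGA belong to the liver and gut list and count in its summed CPM in section 3. APOB, an apolipoprotein gene, had 724 counts, AvBD10, a beta-defensin gene, had 508, and TTR, which encodes transthyretin, had 342. The fibrinogen genes FGG and FGA had 291 and 199 counts. These 5 genes are given as a signal in data outside the gene and list tests, and no test was made of their levels. The separate tissue piece of 46 pixels in section 3, with 4.30% of that section's counts, held 98.6% of the APOB counts (95% Wilson interval 97.5 to 99.2), 98.0% of AvBD10 (96.4 to 98.9), 98.2% of TTR (96.2 to 99.2), 97.6% of FGG (95.1 to 98.8) and 97.0% of FGA (93.6 to 98.6). Counting intervals cover counting error only, and no biological explanation was tested.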

How the results depend on the processing

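Of the alternatives here, the largest tissue piece alone, the removal of row 24 with ribosomal RNA, epithelial-low pixels alone and matching in bands of 5 rows were chosen after seeing the data. For epithelial-high against epithelial-low pixels, 661 of 669 values of 48 named genes kept direction and side of the threshold, 7 fell short of it and 1 reversed: ALDH1A2, at 0.32 with the score from the pixel alone. The 2611 genes became 1463 with no replicate block and 1445 in DESeq2, and leaving out each section gave 1734 to 2565. For near against far pixels, 370 of 553 values of 31 named genes were kept, 175 fell short and 8 newly passed, and 28 of the 31 genes changed side without section 1. The 127 genes became 376 with no filter, 2 with no replicate block, 69 after thinning to equal totals, 38 in DESeq2, 61 with all deposited pixels, 25 with a buffer of 2.5 steps and 284 with no buffer. They became 62 and 75 with the top 10% and top 30% as epithelial-high, 73 in epithelial-low pixels only and 72 in the largest piece, and leaving out each section gave 0 to 64. The 0, from edgeR without section 1, stood beside 760 of 9814 tested genes at an unadjusted p under 0.05, where 5% would lie by chance. The 10 lists shifted between epithelial-high and epithelial-low pixels became 0 with an estimated correlation and 10 to 11 without each section. The 6 lists shifted between near and far became 0 with an estimated correlation, 3 with a buffer of 2.5 steps, 3 in epithelial-low pixels only, 10 matched in bands of 5 rows, 2 with the top 30% and 3 to 8 without each section. The test direction reversed for neuron and neural crest with a buffer of 2.5 steps (median log2 fold 0.053), and for interstitial matrix and retinoic acid matched in bands of 5 rows, although their medians stayed positive (0.0268 and 0.142). Counts per pixel in epithelial-high over epithelial-low pixels gave 0.968 to 1.08 without each section, and near over far gave 0.991 with a buffer of 2.5 steps and 1.07 to 1.14 without each section. The correlation of TGF-beta with condensation was 0.281 over all pixels and 0.0103 to 0.0751 without each section. Patterned genes were 367 at a mean of 0.5 counts, 278 centred within channels and 754 to 1037 without each section, and clusters were 7 at resolution 0.3. The estimated correlation widens the spread each list is tested against, the count minimum leaves fewer genes to test, and for the other changes the cause was not tested. In simulations at this depth, 28% of genes changed 1.5-fold between epithelial-high and epithelial-low pixels were recovered and 22% between near and far.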

Other observations

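Matching in bands of 5 rows, the comparison of epithelial-high with near pixels for carried-over RNA and the estimate of its share were chosen only after earlier results had been seen. Profiles by distance from the epithelium were also taken for other genes and lists, without a test. ALDH1A2, the enzyme that makes retinoic acid, stood at 49.5 ± 21.3 CPM (SD, n = 3) in epithelial-high pixels, 41.7 ± 16.4 CPM within 1.5 steps and 222 ± 41.1 CPM from 2.5 to 3.5 steps. Mesothelium genes, with ALDH1A2 among them, stood at 148 ± 42.8 CPM within 1.5 steps and 473 ± 36.9 CPM from 2.5 to 3.5 steps. Endothelium genes stood at 108 ± 48.8 CPM in epithelial-high pixels and 490 ± 136 CPM from 1.5 to 2.5 steps, and the bin with their highest value differed between the sections.

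Regions found by clustering also differed in where they lay. Of the pixels in region 3, led by HOXB8 and SALL1, 48.5% were far and 20.7% near, and of those in region 9, led by FOXD3 and SOX10, 45.3% were far and 13.9% near. Region 7, led by PITX1, had 34.4% of its pixels near and 13.9% far, and region 8, led by EBF3, 31.2% near and 16.9% far. Region 4, led by NCAM2, GRIK2 and HHIP, had 26.1% of its pixels in the epithelial-high region and 3.502% far.

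The 2611 genes that separate epithelial-high from epithelial-low pixels were set against other divisions of the same tissue. Of the 10 splits of the 6 summed libraries, 1, the real one, gave as many genes, and the highest other gave 0 in edgeR, but 10 splits are too few for a share under 0.05. Random smooth fields with the same shares of pixels gave as many genes in 0 of 50 draws, with at most 67 genes and a median of 3. Each field was drawn separately in each section and matched to the real score only on Moran's I of neighbouring pixels. The draws therefore argue only against smooth divisions of that scale unrelated between sections. An axis that the sections share was not tested. No biological explanation was tested, since the labels give 1 group.

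The 127 genes between near and far pixels rest on less. Of the 10 splits of the libraries 1, the real one, gave as many, with 7 in the highest other, again too few splits for a share under 0.05. Random smooth fields gave as many in 0 of 50 draws, with at most 45 and a median of 0.5. These fields too were drawn separately in each section, so they cannot speak on an axis that the sections share. They were matched to the real distances only on Moran's I of neighbouring pixels, with smoothing kernels of SD 3, 1 and 2 pixels. Coarser divisions were not tried, although near and far lay at median rows 31 and 10 in section 1 and 23 and 41 in section 3. The draws therefore cannot decide on smooth divisions at that coarser scale. Epithelial RNA carried into neighbouring pixels could lift a gene near the epithelium only towards its level in epithelial-high pixels. Among the 82 genes higher near, 73 were lower in epithelial-high than in near pixels. The median log2 ratio of epithelial-high over near was -1.16 (95% interval over genes -1.38 to -0.96). The genes were chosen for being higher near, and the same near counts enter this ratio, which draws it below 0. With that limit, the values argue against carried-over RNA for those 73 genes. For the other 9 the test cannot decide. The carried share on 35 other epithelial genes was 0.2401%, 1.16% and -0.0612% in sections 1, 2 and 3. Such a share would bring a log2 lift of at most 0.06, that of SOX9. The observed values were 2.63 for SOX9 and at least 0.71 for each of the others. Genes called between near and far were left out of the 35, which draws this share towards 0. On the defining genes the share was -6.13%, -1.86% and -2.30%, as far pixels held more of them than near pixels. Mixing cannot give a share below 0. Position along the rows cannot be told apart from distance here, and whether it accounts for part of the differences stays open. Matched in bands of 5 rows, the median ratio of matched to unmatched log2 fold was 0.668 (95% interval over genes 0.603 to 0.726). That lies between the 0.5 that rows as the main cause would need and the 0.8 that would speak against them. A ratio below 1 can also come from choosing the genes in the unmatched fit. Matching also lowered the mean distance of far pixels. It went from 7.70 to 5.52 steps in section 1, from 5.65 to 5.53 in section 2 and from 8.95 to 7.31 in section 3.

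A hypothesis from the distance profiles is that TGFB2 may be higher in mesenchyme far from the epithelium. Over all pixels the log2 ratio of TGFB2, far over near, was 0.61 ± 0.44 (SD, n = 3), at 1.11, 0.44 and 0.28 in the sections, and the edgeR adjusted p of 0.0789 did not pass, in a range from 0.000185 to 0.64 over its alternatives. If the tissue edge were the whole cause, the ratio would lie at or near 0 among pixels more than 2 steps from empty positions, and it was 0.984 ± 0.512 there. If regions rich in mesothelium genes were the whole cause, it would do so without them, and it was 1.13 ± 0.220. Matched in bands of 5 rows, the edgeR log2 fold of TGFB2, near over far, was -0.64 against -0.59 unmatched. Row position as the whole cause would need a fold near 0, which was not seen there. The match was 1 random draw, with 65, 147 and 101 pixels per region in sections 1, 2 and 3. In section 1 its near pixels held 1.75 times the counts of its far pixels. Row position as part of the cause stays open, and no biological explanation was tested.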
